A study of Mus musculus with 6 samples.

How the data were processed

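Gene expression was measured on 6 Affymetrix microarrays, each hybridised with labelled total RNA of the mouse myoblast line C2C12. The labels place 3 arrays in a group transfected with a pool of small interfering RNAs (siRNAs) against Htt, the mouse huntingtin gene, and 3 arrays in a control group transfected with scramble siRNA. The labels of the treated group use the word knockout, while the series' design text and the treatment protocol describe siRNA, so the group is called Htt siRNA or knockdown here. The labels do not say whether replicates came from separate cultures. All p-values therefore measure the spread between these samples, which may be technical. The time after transfection and the culture stage at harvest are not given in the sources used here. The design text mentions a further cell line, which is not analysed here. The labels' protocols name an in vitro transcription labelling kit, while the probe set identifiers are of the kind used on whole-transcript arrays, so how the RNA was labelled stays open.

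The authors deposited 1 table of log2 expression values for 41345 probe sets, a probe set being a group of probes summarised to 1 value. The submitters' processing notes name RMA (background correction, quantile normalization and probe summary) and the affy package, without versions. Quantile normalization gives arrays the same overall distribution, so a change in total RNA per cell leaves no trace in these values, and weak signals are compressed towards the background. The deposited values spanned 0.84 to 12.12 on the log2 scale, the medians of the arrays lay between 2.59 and 2.67, and no value was missing. Pairs of arrays correlated with r between 0.981 and 0.991 across probe sets, which are not independent replicates, and no pair held identical values throughout. The table holds no detection calls, so no statement is made that a gene was absent. The number of arrays limits the precision of every value.

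Gene names came from the platform annotation, which listed 25335 of the probe sets and left 16010 unnamed here. Of the listed probe sets, 23521 had 1 gene symbol and 1814 had several. Of those with 1 symbol, 23328 were found by Entrez identifier in a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols needed an update. No coordinates are printed because the sources used here name no genome build for the array. For each of 22180 genes, the probe set with the highest mean over the 6 arrays, among those with 1 symbol, stood for the gene; 1082 genes had several probe sets. No filter on dim genes was applied.

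Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on the deposited log2 values with the group as the only term. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 22180 genes with a threshold of 0.05. Log2 fold changes are Htt siRNA minus scramble, given with the moderated standard error (SE), for 3 arrays per group. A fold of at least 2 was counted as a description. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

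Before the data were examined, 31 gene lists were written, with 918 entries of which 845 were measured. They cover myogenic transcription factors, Id and Notch inhibitors of myogenesis, adhesion and fusion, sarcomere, neuromuscular junction with excitation-contraction coupling, extracellular matrix, mitosis, S phase, cell cycle inhibitors with p53 targets, chaperones, the unfolded protein and integrated stress response, interferon response, inflammatory cytokines, cholesterol synthesis, NRF2 targets, oxidative phosphorylation, mitochondrial biogenesis, glycolysis with hypoxia, autophagy with lysosome, ubiquitin-proteasome with atrophy, huntingtin partners, REST-regulated neuronal genes, TGF-beta targets, serum response, insulin-like growth factor signalling, ribosomal proteins and 5 sets of markers of other cell types. Each list was tested with camera (preset inter-gene correlation 0.01), which compares its genes with all other genes, and adjusted over the 31 lists. Camera with the correlation estimated from the residuals and fry were alternatives. Adjustment can give lists with different p the same adjusted p. Members were also counted at a threshold of 0.05 adjusted over the list alone. The mean of a list's members in each array is called its level, and levels were compared by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1.

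The rule for named genes was also fixed before the data were examined. It names Htt, then up to 12 genes per direction past the threshold or, where fewer than 5 pass, the 5 with the smallest p per direction. For each list it names up to 3 members past the threshold or, with none past it, the 2 members with the largest absolute log2 fold change among those above the median expression. Genes without an assigned name are skipped. Other genes named were chosen after their values were seen and are marked so.

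The steps were tested on simulated data for the comparison of 3 against 3 arrays, with 22180 genes of which 200 were changed, in 20 simulations. The limma fit called 87.6% of 2-fold and 99.2% of 4-fold changes, and on average 4.5% of calls were false. The noise of each gene was drawn independently from the spread fitted in limma, without structure shared between arrays. The real arrays held such structure, so these rates cannot be carried over to them. In the real data 107 genes reached a 2-fold change and 0 passed the threshold. With the preset correlation, camera called 0 of 620 unchanged lists and called a sarcomere list shifted by 0.40 in 20 of 20 simulations. A shifted list was not tried with the estimated correlation, so the power of that version is not known here. When an unchanged S phase list was given the observed spread of its level between arrays (SD 0.48, log2), camera with the preset correlation called it in 10 of 20 simulations, and with the estimated correlation in 0 of 20.

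Alternatives were the replicate number as a block, a filter on genes below the median level, quantile normalization repeated, centring of each array on its median, the mean of a gene's probe sets, an intensity trend or a robust prior in eBayes, array weights, all probe sets tested, and leaving out each array in turn. The level of the stress response list as a covariate was added after seeing the data.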

Results

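The series profiled gene expression in C2C12 cells, a mouse myoblast line that fuses into contractile myotubes when serum is withdrawn, after siRNA against huntingtin (Htt), the gene whose expanded human form causes Huntington's disease. By its title the study asks whether huntingtin regulates muscle differentiation in culture. There were 3 arrays of cells given an Htt siRNA pool and 3 of cells given scramble siRNA, and expression is given as deposited log2 RMA values for 22180 genes. All comparisons below are Htt siRNA against scramble, tested with limma, and log2 fold changes are followed by their standard error.

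Htt was lower in all 3 knockdown arrays. Its log2 level was 4.54 ± 0.10 with Htt siRNA and 5.64 ± 0.08 with scramble (mean ± SD, n = 3 each), measured by probe set 17436683. The 3 knockdown arrays stood at 4.49, 4.47 and 4.65 and the 3 scramble arrays at 5.59, 5.60 and 5.72, so the groups did not overlap. The log2 fold change was -1.10 ± 0.09, which left 46.6% of the scramble level (95% confidence interval 40.2 to 53.9%). Because weak signals are compressed in RMA values, the true share may be lower, and the interval does not cover this. Single knockdown arrays held 45.2%, 44.4% and 50.3% of the scramble mean. Htt had the smallest p of all genes, with an adjusted p of 0.0559 in limma that just missed the threshold. Without Htt siRNA replicate 2 its adjusted p was 0.00778. Over all alternatives run, the adjusted p lay between 0.00778 and 0.348 and the log2 fold change between -1.16 and -1.04.

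No gene passed the threshold over all genes, and those with the smallest p are given as values. Higher after Htt siRNA were C1qtnf3, a secreted C1q and TNF related protein (log2 fold change 1.91 ± 0.17, adjusted p = 0.0559), Lrp4, the receptor for agrin at the neuromuscular junction (1.42 ± 0.15, adjusted p = 0.106), the microRNA gene Mir1945 (0.92 ± 0.11), Rps27, a ribosomal protein (0.86 ± 0.11), and Pdgfrl, a platelet-derived growth factor receptor-like protein (0.83 ± 0.11). Lower values after Htt siRNA, besides Htt, were found for Serpinb9e, from a cluster of closely related serine protease inhibitors (-2.81 ± 0.27, adjusted p = 0.0683), Aldh3a1, an aldehyde dehydrogenase (-1.66 ± 0.21), Plet1, a surface protein (-1.12 ± 0.13), and Sgk1, the serum and glucocorticoid regulated kinase (-0.98 ± 0.13). The last 3 and Mir1945, Rps27 and Pdgfrl shared an adjusted p of 0.125. With scramble, Mir1945 averaged 2.94, close to the median gene mean of 2.95 and so near the background. Rps27 averaged 4.51 there, well below the level of the ribosomal protein list (7.29). Limma called 0 of 22180 genes at the adjusted threshold, while 2409 had an unadjusted p under 0.05, of which 1269 were higher and 1140 lower, against 1109 expected by chance. After centring the arrays on their medians that split was 911 higher and 1465 lower. A fold of at least 2 was reached by 32 genes upwards and 75 downwards. In 15.98% of genes the 2 groups did not overlap, where chance gives 10%. The count of called genes rested on the arrays used: without Htt siRNA replicate 2 it was 540 (117 higher and 423 lower), and without scramble replicate 1 it was 1.

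**Figure D1:**
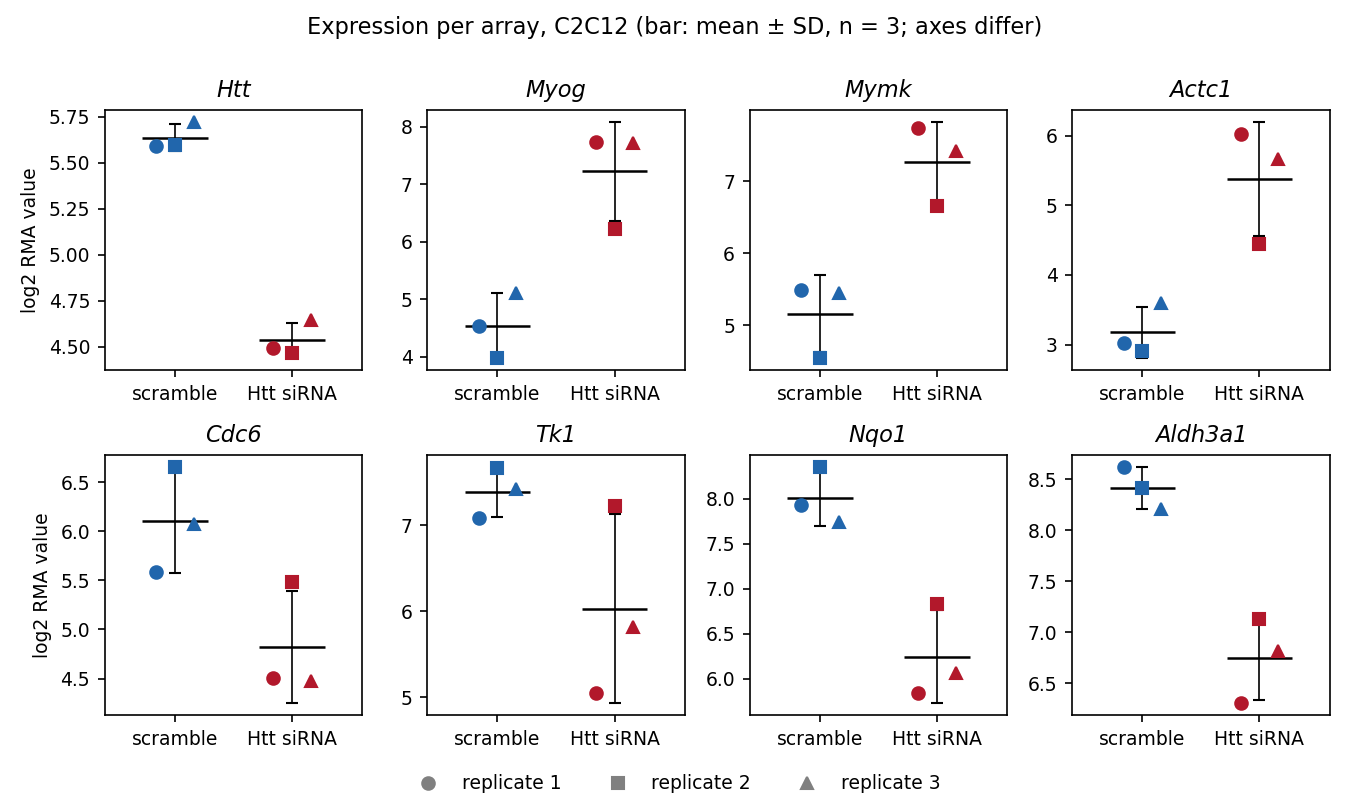
Log2 RMA values (vertical axes, which differ between panels) of 8 genes in the 3 scramble arrays (blue) and the 3 Htt siRNA arrays (red); symbols mark the replicate number, horizontal bars the group mean and vertical bars the SD. Htt lies at 4.47 to 4.65 with Htt siRNA against 5.59 to 5.72 with scramble, and Myog averages 7.22 against 4.54.

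Among the muscle regulators, Myog stood out. Myogenin, the transcription factor that starts terminal differentiation of myoblasts, rose at the threshold adjusted over the list alone, from a log2 level of 4.54 ± 0.57 to 7.22 ± 0.87 (SD, n = 3), a 6.42-fold difference (2.68 ± 0.44, adjusted p = 0.169 over all genes and 0.00446 over the list alone). It was the only 1 of 14 myogenic transcription factors past that threshold, with 0 lower, and this held without each array in turn, while repeated quantile normalization gave 2. Myod1, which commits cells to the muscle lineage, had a log2 fold change of 0.66 ± 0.27 and did not pass. Camera placed the list above other genes (median 0.18, adjusted p = 0.0156), with an adjusted p = 0.429 with an estimated correlation. The camera call was lost without Htt siRNA replicate 2 (adjusted p = 0.0745) and without scramble replicate 1 (0.0994), and with array weights (0.0587).

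Of 26 adhesion and fusion genes, 3 rose adjusted over the list alone and 0 fell. These were Mymk, which encodes the fusion protein myomaker (2.11 ± 0.33, 4.32-fold), the muscle membrane protein gene Tmem182 (1.17 ± 0.19) and the adhesion molecule gene Ncam1 (0.49 ± 0.12), the last chosen after its value was seen. Camera did not call this list (median 0.09, adjusted p = 0.076), but did without Htt siRNA replicate 1 (0.0389), scramble replicate 2 (0.0299) or scramble replicate 3 (0.0211), above the median level (0.0249) and with centred arrays (0.0433). Leaving out Htt siRNA replicate 2 gave 4 higher and 2 lower members, and leaving out scramble replicate 1 gave 3 higher and 1 lower. Of 20 Id and Notch genes that restrain myogenesis, Hey1, a Notch target, rose adjusted over the list alone (0.85 ± 0.19) and 0 fell. The repressor Msc had a value of -0.40 ± 0.19. Camera did not call the list (adjusted p = 0.744). The Hey1 call was lost without Htt siRNA replicate 1, Htt siRNA replicate 3 or scramble replicate 3, and with arrays centred on their medians.

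Genes of the contractile apparatus lay higher after Htt siRNA. Of 47 measured sarcomere and contractile genes, 23 rose adjusted over the list alone, 0 fell and 24 did not pass, while 0 passed over all genes; 42 of the 47 had positive fold changes. Actc1, the cardiac actin that embryonic skeletal muscle also uses, rose 4.61-fold (2.21 ± 0.38) and Mylpf, the fast myosin regulatory light chain, 4.19-fold (2.07 ± 0.50). Among members chosen after their values were seen, the fast troponin gene Tnnt3 rose by 1.84 ± 0.37, skeletal actin Acta1 by 1.35 ± 0.23, the giant protein genes Ttn by 1.31 ± 0.31 and Neb by 1.25 ± 0.21, and embryonic myosin Myh3 by 0.58 ± 0.15, all log2. The median of the list was 0.37, and its level was 4.18 ± 0.18 with Htt siRNA against 3.64 ± 0.13 with scramble, with no overlap between arrays (SD, n = 3; exact two-sided permutation p = 0.1, the smallest this design allows). Camera gave an adjusted p = 2.54e-14, and an adjusted p = 0.429 with an estimated correlation. The count fell to 10 without Htt siRNA replicate 1, to 3 without Htt siRNA replicate 3 and to 8 without scramble replicate 2, and the median was 0.72 among genes above the median level.

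The neuromuscular junction and excitation-contraction coupling list showed 11 of 27 members that rose adjusted over the list alone, 0 that fell and 16 that did not pass. Besides Lrp4, these included Chrng, the fetal subunit of the acetylcholine receptor (1.70 ± 0.35, 3.24-fold), and Trdn, the calcium release complex protein triadin (1.48 ± 0.24, 2.78-fold). The calcium release channel Ryr1 (0.74 ± 0.18) and the receptor clustering protein Rapsn (0.79 ± 0.19), both chosen after their values were seen, rose too. The median was 0.43 and the list's level was 4.93 ± 0.16 against 4.44 ± 0.16 (SD, n = 3; exact two-sided permutation p = 0.1). Its adjusted p was 8.89e-11 in camera, and an adjusted p = 0.429 with an estimated correlation. The count was 3 without Htt siRNA replicate 1 and 2 without Htt siRNA replicate 3, and the median was 0.22 without scramble replicate 2.

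Extracellular matrix genes moved in both directions with more members higher. Of 38 measured, 14 rose and 3 fell adjusted over the list alone, and 21 did not pass. The collagen-binding proteoglycan decorin (Dcn) rose 3.22-fold (1.69 ± 0.30) and Col1a1, the main fibrillar collagen chain, 2.25-fold (1.17 ± 0.23). Of members chosen after their values were seen, Postn (1.04 ± 0.28) and Col12a1 (0.80 ± 0.11) also rose, while the members that fell were the matrix protein Fbln1 (-0.41 ± 0.12), the metalloproteinase inhibitor Timp1 (-0.41 ± 0.13) and the basement membrane protein Nid1 (-0.40 ± 0.13). In camera, the list had an adjusted p = 4.99e-05 upwards (median 0.18), and an adjusted p = 0.46 with an estimated correlation. The number that rose was 5 without Htt siRNA replicate 1, 6 without Htt siRNA replicate 3 and 7 without scramble replicate 2, and the number that fell was 0 when any array other than Htt siRNA replicate 2 was left out; the median was 0.31 without scramble replicate 3.

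**Figure D2:**
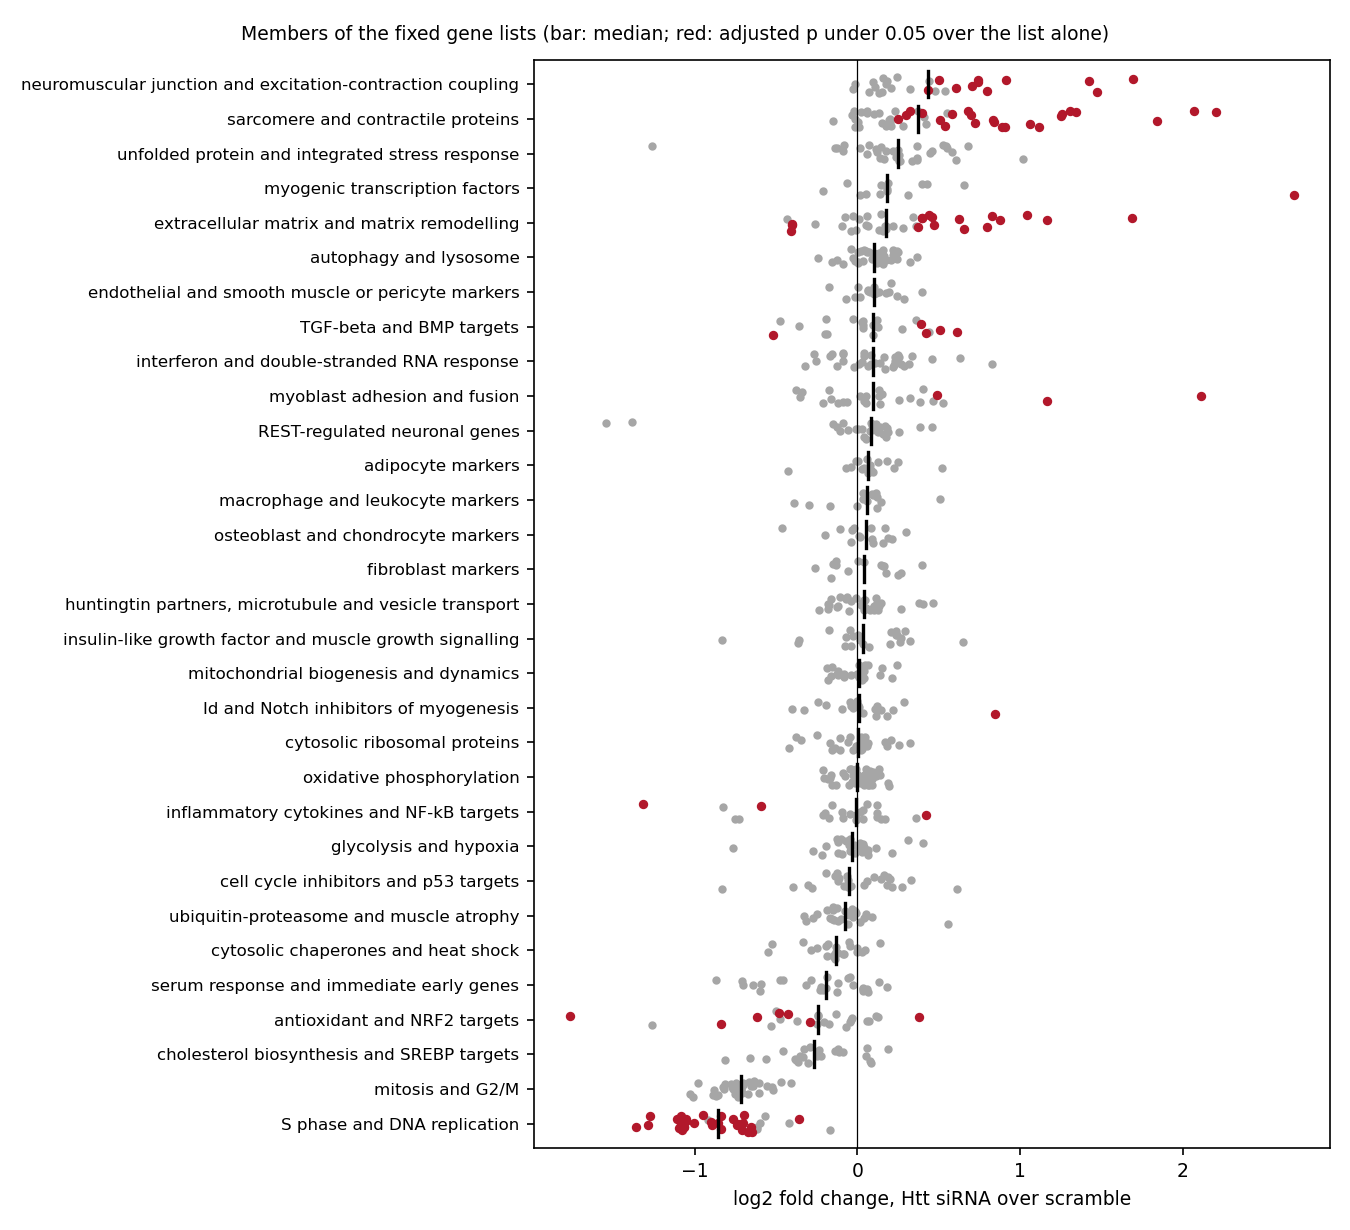
Log2 fold change (horizontal axis, Htt siRNA over scramble) of every measured member of the 31 gene lists, 1 point per gene; black bars are list medians and red points have an adjusted p under 0.05 over the list alone. The 37 S phase members and 38 mitosis members all lie below 0 (medians -0.86 and -0.72), and 42 of 47 sarcomere members lie above 0.

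The unfolded protein and integrated stress response list separated the arrays across the groups. Its level relative to the 6-array mean was 0.64 and 0.66 in Htt siRNA replicates 1 and 3 and 0.73 in scramble replicate 1, against -0.95 in Htt siRNA replicate 2, -0.68 in scramble replicate 2 and -0.39 in scramble replicate 3. The difference between the groups was smaller than the spread within them (7.80 ± 0.92 against 7.57 ± 0.75, SD, n = 3; exact two-sided permutation p = 1). Of 33 members, 0 passed limma's threshold over the list alone and 0 had an unadjusted p under 0.05, with values of 1.02 ± 0.87 for the chaperone cofactor Sdf2l1 and -1.27 ± 1.00 for Slc7a11. Camera gave an adjusted p = 0.252 upwards. Without Htt siRNA replicate 2 it was 3.09e-08, with 3 higher members, and without scramble replicate 1 it was 6.65e-05; it also passed above the median level (0.0271) and with array weights (0.00193), while the direction turned without Htt siRNA replicate 1 (0.69), Htt siRNA replicate 3 (0.817) or scramble replicate 2 (1). This list's level in each array, used as a covariate in limma, is called the stress covariate; with it 85 genes passed the threshold (28 higher and 57 lower), and 1 of the list's own members was lower over the list alone.

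Genes of cell division lay lower after Htt siRNA. Of 37 S phase and DNA replication genes, 30 fell adjusted over the list alone, 0 rose and 7 did not pass; the median was -0.86. Tk1, the thymidine kinase of S phase, fell 2.57-fold (-1.36 ± 0.48) and the origin licensing factor Cdc6 2.44-fold (-1.29 ± 0.33). Among members chosen after their values were seen, the replicative helicase genes Mcm2 to Mcm7 fell by log2 values from 0.90 (Mcm7, -0.90 ± 0.29) to 1.28 (Mcm3, -1.28 ± 0.45). All 38 mitosis genes had negative fold changes, with a median of -0.72 (-0.47 without Htt siRNA replicate 1). Yet 0 passed limma's threshold adjusted over the list alone, while 29 had an unadjusted p under 0.05. For S phase that unadjusted count was 30, so the lists differed little before adjustment. The smallest limma p adjusted over the list alone was 0.0389 for S phase and 0.0629 for mitosis. Members of each list moved together, with a correlation estimated by camera of 0.87 for S phase and 0.936 for mitosis. Neither count is therefore one of independent genes. Kif23, a kinesin of cytokinesis (-1.03 ± 0.33), and Birc5, the mitotic protein survivin (-1.01 ± 0.34), had the largest values by the naming rule. Against all other genes, camera returned an adjusted p = 4.17e-24 for S phase and 2.58e-22 for mitosis, and an adjusted p = 0.429 for each with an estimated correlation.

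The 3 knockdown arrays were unequal in these lists. Relative to the mean of the 6 arrays, the S phase level was -0.89 and -0.66 in Htt siRNA replicates 1 and 3 but 0.26 in replicate 2, which lay between scramble replicate 1 (0.13) and scramble replicate 3 (0.45), with scramble replicate 2 at 0.70. The mitosis level was -0.84, 0.31 and -0.56 in Htt siRNA replicates 1, 2 and 3 and 0.14, 0.56 and 0.39 in the scramble arrays. With that overlap the exact two-sided permutation p was 0.2 for each list (n = 3). The S phase count of 30 became 0 without Htt siRNA replicate 1, Htt siRNA replicate 3, scramble replicate 2 or scramble replicate 3, and with repeated quantile normalization. The mitosis count became 38 lower without Htt siRNA replicate 2, with array weights and with the stress covariate. Of 27 cell cycle inhibitors and p53 targets, 0 passed over the list alone and 1 had an unadjusted p under 0.05 in limma, with values of 0.61 ± 0.18 for the p53 target Pmaip1 and -0.83 ± 0.42 for the G2 and S phase protein gene Gtse1. Leaving out Htt siRNA replicate 2 gave 1 lower member.

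**Figure D3:**
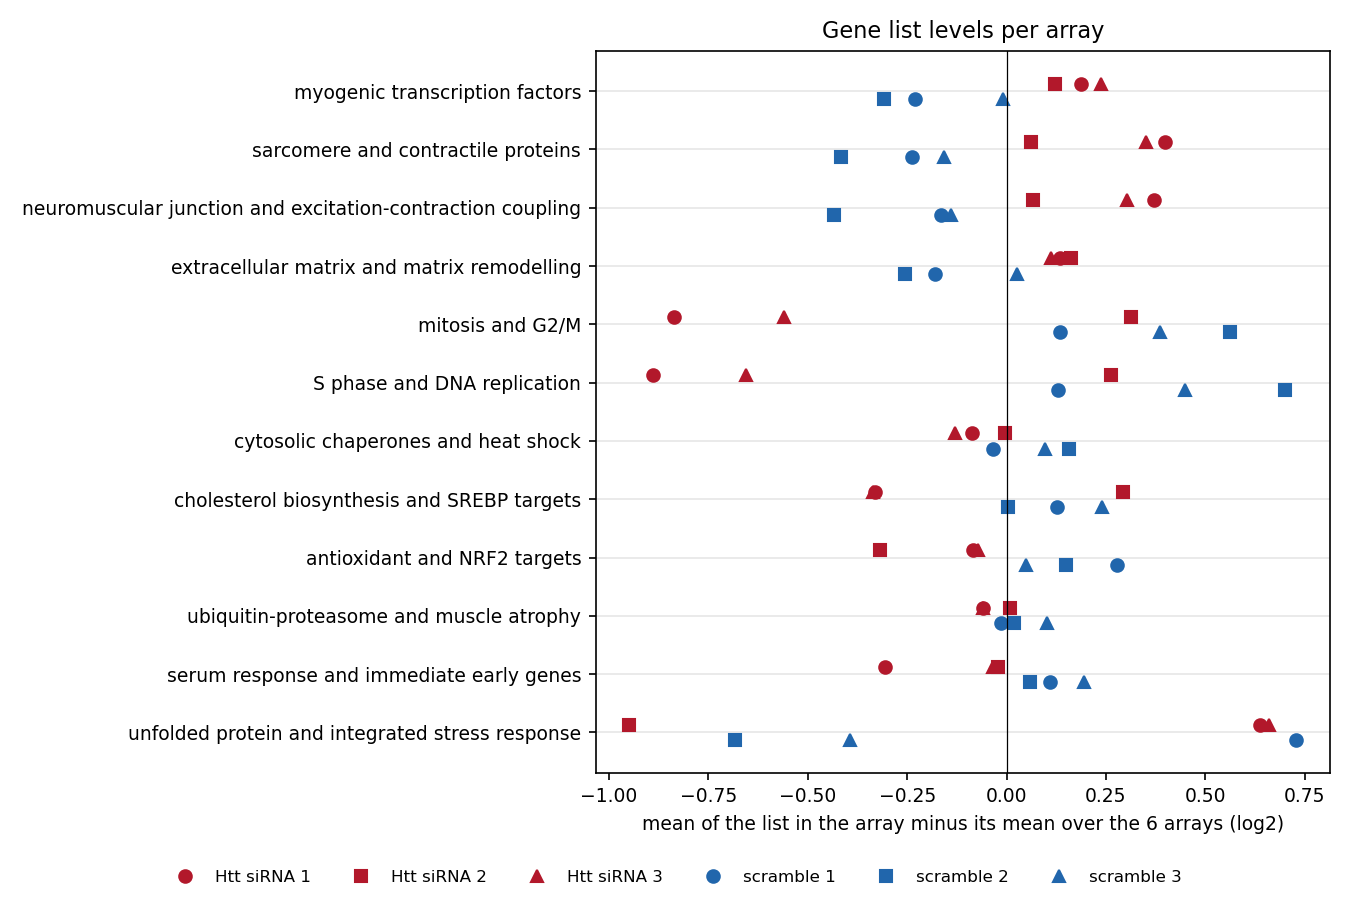
Level of 12 gene lists in each of the 6 arrays (horizontal axis: mean log2 value of the list in the array minus its mean over the 6 arrays; red, Htt siRNA; blue, scramble; symbols, replicate number). Htt siRNA replicate 2 stands at 0.26 for S phase, among the scramble arrays, and at 0.06 for the sarcomere, above all scramble arrays.

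Antioxidant and detoxification genes that NRF2 controls lay lower. Of 26 measured, 6 fell and 1 rose adjusted over the list alone, and 19 did not pass. Nqo1, the quinone reductase used as an NRF2 reporter, fell 3.40-fold (-1.77 ± 0.26), from 8.01 ± 0.31 to 6.25 ± 0.52 (SD, n = 3). Of members chosen after their values were seen, the glutathione transferase Gsta4 (-0.84 ± 0.16), glutathione reductase Gsr (-0.62 ± 0.15), the glutathione synthesis subunit Gclm (-0.48 ± 0.13), thioredoxin reductase Txnrd1 (-0.42 ± 0.10) and ferritin heavy chain Fth1 (-0.29 ± 0.09) fell, and the secreted glutathione peroxidase Gpx3 rose (0.38 ± 0.11). The cystine transporter Slc7a11 had a value of -1.27 ± 1.00. The level of the list was lower in each knockdown array than in each scramble array (7.20 ± 0.14 against 7.51 ± 0.11, SD, n = 3; exact two-sided permutation p = 0.1). In camera, the list had an adjusted p = 7.75e-08, and an adjusted p = 0.202 with an estimated correlation. The number that fell was 2 without Htt siRNA replicate 1, 2 without scramble replicate 2, 3 without scramble replicate 1 and 11 with the stress covariate, and Gpx3 did not pass without Htt siRNA replicates 1 or 2 or scramble replicates 2 or 3, nor among genes above the median level.

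Camera also placed 4 further lists below other genes, in which 0 members passed limma's threshold adjusted over the list alone. For 27 serum response and immediate early genes (median -0.20, and -0.10 without Htt siRNA replicate 1; adjusted p = 1.41e-05), 7 had an unadjusted p under 0.05, and values included Dusp6, a phosphatase of ERK (-0.87 ± 0.40), and Ier3 (-0.71 ± 0.17). For 25 cytosolic chaperones (median -0.14, and -0.09 without Htt siRNA replicate 3; adjusted p = 8.69e-05), 3 had an unadjusted p under 0.05, with Hsph1 at -0.55 ± 0.23 and the heat shock gene Hspa1b at -0.52 ± 0.36. For 24 cholesterol synthesis and SREBP target genes (median -0.27, and -0.14, -0.49 and -0.16 without Htt siRNA replicates 1, 2 and 3; adjusted p = 0.000136), 0 had an unadjusted p under 0.05, with the sterol sensor Insig1 at -0.82 ± 0.38 and the sterol carrier Stard4 at -0.66 ± 0.31. For 27 ubiquitin-proteasome and atrophy genes (median -0.08, and -0.13 without scramble replicate 1 and -0.12 with array weights; adjusted p = 0.0038), 3 had an unadjusted p under 0.05, with the proteasome subunit Psma1 at -0.33 ± 0.13 and the atrophy ligase Fbxo32 at 0.56 ± 0.19. With an estimated correlation the adjusted p was 0.429 for the serum response, chaperone and proteasome lists and 0.619 for the cholesterol list. The proteasome call was lost without scramble replicate 3 (adjusted p = 0.0732) and among genes above the median level (0.105). Members lower over the list alone numbered 16 for cholesterol without Htt siRNA replicate 2, where replicate 2 stood at 0.29 against -0.33 and -0.34 in replicates 1 and 3 relative to the 6-array mean. For the serum response they numbered 7 without Htt siRNA replicate 2, 1 without Htt siRNA replicate 3 and 4 without scramble replicate 1, 8 with the stress covariate, 5 with array weights and 4 with centred arrays.

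Signalling lists held a few members that passed over the list alone without a camera call. Of 23 TGF-beta and BMP targets, 4 rose and 1 fell. The smooth muscle type genes Tagln (0.61 ± 0.13), Cnn1 (0.51 ± 0.14) and Acta2 (0.42 ± 0.08) and the ligand Tgfb2 (0.39 ± 0.10) rose, and Smad7, an inhibitor of TGF-beta signalling, fell (-0.52 ± 0.09); Cnn1, Acta2 and Tgfb2 were chosen after their values were seen. Camera gave an adjusted p = 0.322. The number that rose was 2 without Htt siRNA replicate 1, scramble replicate 1 or scramble replicate 2, and the number that fell was 3 without Htt siRNA replicate 2 and 2 with array weights or the stress covariate. Of 25 inflammatory and NF-kB target genes, 2 fell and 1 rose: the monocyte chemokine Ccl2 (-1.32 ± 0.25, 2.49-fold) and the neutrophil chemokine Cxcl1 (-0.59 ± 0.12) fell and the chemokine Ccl20 rose (0.42 ± 0.08), the last 2 chosen after their values were seen. Ccl7 had a value of -0.82 ± 0.31. In camera, the list had an adjusted p = 0.093, which passed without Htt siRNA replicate 3 (0.0486) and without scramble replicate 3 (0.0453); the number that fell was 4 with the stress covariate. Of 34 interferon and double-stranded RNA response genes, which siRNA itself can induce, 0 passed and 4 had an unadjusted p under 0.05. Irf9 had a value of 0.83 ± 0.25 and Xaf1 of 0.63 ± 0.22. In camera, the list had an adjusted p = 0.194, which was 0.00793 without Htt siRNA replicate 2 and 1.45e-05 without scramble replicate 2, with 1 higher member in the former and 1 with the stress covariate. Of 23 insulin-like growth factor and muscle growth genes, 0 passed and 5 had an unadjusted p under 0.05 (Hgf -0.83 ± 0.27, Igfbp4 0.65 ± 0.28, camera adjusted p = 0.64). Without Htt siRNA replicate 2, 1 rose and 1 fell.

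The lists of energy metabolism, autophagy, huntingtin partners, neuronal and ribosomal genes showed no member past limma's threshold over the list alone, and camera called none of them. Of 42 oxidative phosphorylation genes, 0 had an unadjusted p under 0.05 (median -0.003, Ndufb3 -0.21 ± 0.21, cytochrome c gene Cycs -0.20 ± 0.09, adjusted p = 0.552). Of 24 mitochondrial biogenesis genes, 1 had (median 0.01, Pink1 0.24 ± 0.11, adjusted p = 0.56); Tfb2m had a value of 0.21 ± 0.09, and another of its probe sets -0.26. Glycolysis and hypoxia had 0 of 26 (median -0.04, Egln3 -0.77 ± 0.34, Ndrg1 0.40 ± 0.42, adjusted p = 0.252). Autophagy and lysosome had 2 of 37 (median 0.10, Hexa 0.37 ± 0.16, Map1lc3a 0.32 ± 0.14, adjusted p = 0.076). That list's median was 0.03 without Htt siRNA replicate 1 and 0.06 without scramble replicate 2. Camera passed for it without Htt siRNA replicate 2 (0.0142), scramble replicate 1 (0.0193) or scramble replicate 3 (0.0453), above the median level (0.00505), with repeated quantile normalization (0.00638) and with array weights (0.0349). Huntingtin partners and transport genes had 2 of 33 (median 0.04, the kinesin gene Kif5c 0.46 ± 0.12, the dynein light chain gene Dynll1 0.41 ± 0.19, adjusted p = 0.744), and 1 was higher over the list alone with repeated quantile normalization. Of 28 REST-regulated neuronal genes, 4 had an unadjusted p under 0.05, and the neurofilament genes Nefl (-1.54 ± 0.45) and Nefm (-1.39 ± 0.47) had the largest values. That list's median was 0.09 and its mean -0.02, with camera upwards (adjusted p = 0.346), and without Htt siRNA replicate 2 it had 3 higher and 2 lower members and with the stress covariate 2 lower. Of 32 ribosomal protein genes, 0 had an unadjusted p under 0.05 (Rps23 -0.42 ± 0.31, Rpl30 -0.38 ± 0.18, adjusted p = 0.524). Median, mean and camera also differed in sign for the ribosomal list (0.003, -0.02 and downwards) and the mitochondrial biogenesis list (0.01, -0.01 and downwards). Camera's direction turned in some settings, without a call, for the Id and Notch, p53, growth factor, oxidative phosphorylation, mitochondrial biogenesis, huntingtin partner, ribosomal, adipocyte and macrophage lists.

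Markers of other cell types showed no call. Over the list alone 0 members passed in limma in each of the 5 lists, and the unadjusted p was under 0.05 for 1 of 17 adipocyte, 1 of 16 osteoblast and chondrocyte, 2 of 15 fibroblast, 3 of 15 macrophage and leukocyte, and 1 of 19 endothelial and smooth muscle markers. Their median log2 fold changes over all members lay between 0.04 and 0.10, but most members lay below the median level of all genes. Among members above it the medians were -0.04 (4 adipocyte), -0.13 (2 osteoblast and chondrocyte) and -0.13 (7 fibroblast). They were -0.30 for 3 macrophage and leukocyte and 0.13 for 7 endothelial and smooth muscle markers. The endothelial and smooth muscle level was higher in each knockdown array than in each scramble array (exact two-sided permutation p = 0.1). Values included Pparg -0.43 ± 0.19 and Dgat2 0.25 ± 0.23 for adipocytes, Sox9 -0.47 ± 0.29 and Col2a1 0.21 ± 0.10 for cartilage, Ddr2 0.40 ± 0.30 and Pdgfra -0.26 ± 0.11 for fibroblasts, Cd68 -0.39 ± 0.14 and Cd14 -0.30 ± 0.12 for macrophages, and Notch3 0.29 ± 0.18 and Cspg4 0.24 ± 0.14 for mural cells. Camera's adjusted p was 0.322, 0.552, 0.747, 0.744 and 0.093 in the order of the lists, the last passing without scramble replicate 3 (0.0371). With array weights, the stress covariate or the mean of probe sets, 1 adipocyte marker was higher over the list alone.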

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

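Of the tests in this part, that of repeated quantile normalization for Htt siRNA replicate 2 was planned before the result was seen; the tests of rank correlations, of a mislabelled array, of a weaker knockdown, of the stress state and of other splits of the arrays were chosen only after it was seen. Data outside the gene comparison held a difference in 2 unnamed probe sets. Probe set 17202587, which the annotation used here does not list, was higher with Htt siRNA by a log2 difference of 1.50 (6.19 ± 0.16 against 4.69 ± 0.06, SD, n = 3; limma, adjusted p = 0.0223 among the 17824 probe sets left out for want of a single gene name, and 0.0517 over all probe sets). Probe set 17519673, annotated to 4 genes and so unnamed here, was lower by -2.48 ± 0.14 (log2, SE; adjusted p = 0.0277 over all probe sets). Control probe sets cannot be told from other unlisted ones here, so probe set 17202587 is not shown to measure a gene. Both were the only ones of the 17824 past the threshold among themselves, and 1587 had an unadjusted p under 0.05.

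Htt siRNA replicate 2 lay nearer to the scramble arrays than to the other knockdown arrays. On the first principal component over genes (48.2% of the variance) it stood at 11.16, against -26.46 and -26.29 for Htt siRNA replicates 1 and 3 and 1.67, 25.34 and 14.57 for the scramble arrays. A mislabelled scramble array is argued against by its Htt level of 4.47, far below the lowest scramble array at 5.59 (SD 0.08), and a weaker knockdown by an Htt level -0.10 relative to the mean of replicates 1 and 3. Its mean correlation with the scramble arrays exceeded that with replicates 1 and 3 by 0.00418 after repeated quantile normalization and 0.00422 before, which decides nothing, because that step moved values by a median of only 0.02 (log2); rank correlations, which no array-wide scaling that keeps the order of genes can alter, differed the same way by 0.0027, so such scaling is argued against. A candidate explanation is a stress state that cut across the groups. Scramble replicate 1 was high in the stress list. Without that list's own genes, it correlated more with Htt siRNA replicates 1 and 3 than the other scramble arrays did. The mean excess was 0.00336 (0.00382 with replicate 1 and 0.0029 with replicate 3). With Htt siRNA replicate 3, however, it exceeded scramble replicate 3 by only 0.000563, and over all probe sets it did not (0.984 against 0.985). Scramble replicate 1 was picked from these same arrays, and 514 genes outside the list followed the stress level. A higher correlation was thus partly built in. It decides nothing and does not test the place of Htt siRNA replicate 2. No culture record is given in the sources used here, so batch, density or handling behind such a state stays open.

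Other splits of the 6 arrays were fitted in the same way. The real split gave 0 genes past the threshold and the highest other split 202; all 10 of 10 splits reach a count of 0 whatever the data, so that share decides nothing. The split with 202 set Htt siRNA replicates 1 and 3 with scramble replicate 1 against the others, and points to a structure of the samples other than the siRNA. For genes with an unadjusted p under 0.05 the real split gave 2409 and the highest other 2816, with 2 of 10 splits as large, the real split included. For lists called by camera the real split gave 11 and the highest other 10, with 1 of 10 as large, the real split itself. With 10 splits a share under 0.05 cannot be reached.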

How the results depend on the processing

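The stress covariate was chosen after seeing the data; the other alternatives were planned. The Htt log2 fold change stayed between -1.16 and -1.04, and its adjusted p passed the threshold with the replicate block (-1.10, adjusted p = 0.0128), above the median level (-1.10, 0.0326), with repeated quantile normalization (-1.04, 0.0494), centred arrays (-1.13, 0.0333), array weights (-1.11, 0.0438) and the stress covariate (-1.11, 0.0192). Leaving out single arrays gave log2 fold changes from -1.16 to -1.06, past the threshold only without Htt siRNA replicate 2 (adjusted p from 0.00778 to 0.348 over the 6 fits). The number of genes past the threshold moved from 0 to 3 above the median level, 3 with repeated quantile normalization, 3 with centred arrays, 2 with an intensity trend, 1 with array weights, 1 with all probe sets tested, 85 with the stress covariate, and from 0 to 540 when single arrays were left out; it was 0 with the mean of probe sets and with a robust prior. Of the 540 genes called without Htt siRNA replicate 2, that array lay on the same side of the scramble mean for 423 (103 of those higher and 320 of those lower) and on the other for 117, and at the median it showed 17.6% of the change. Because these genes were chosen by the difference that replicates 1 and 3 showed, a smaller share in the array left out is partly built in. Above the median level fewer genes were tested; for the other settings the cause was not tested. Of 1065 alternative values of the 71 named genes, 0 turned direction, and the number of these genes past the threshold was 23 with the block, 22 with the stress covariate, 32 without Htt siRNA replicate 2 and 0 to 3 otherwise.

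The labels give both groups the same replicate numbers, and the numbers paired the arrays only in part. Deviations of same-numbered arrays from their group means correlated across genes with r of 0.35, 0.364 and 0.006. The values for replicates 1 and 2 were the highest of all pairs of a knockdown and a scramble array. Htt siRNA replicate 3 correlated best with scramble replicate 1 (0.223), not with its own number. With the replicate block 98 genes passed (41 higher and 57 lower), 80 of them also among the 540. Over the list alone it gave 37 lower mitosis genes (0 without it), 7 lower serum response genes (0), 10 lower NRF2 targets (6), 4 lower NF-kB targets (2), 4 higher transcription factors (1) and 5 higher and 1 lower fusion genes (3 and 0).

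Camera called 11 of 31 lists, and 0 with an estimated correlation or by fry. With an estimated correlation the adjusted p was 0.429 for the sarcomere, neuromuscular junction, mitosis, S phase, chaperone, serum response, transcription factor and proteasome lists. It was 0.46 for the matrix, 0.619 for cholesterol and 0.202 for NRF2 targets. The shared 0.429 came from the adjustment. Before it, p ran from 0.0365 (sarcomere) and 0.0529 (neuromuscular junction) to 0.166 (transcription factors). Fry gave 0.132 for sarcomere and NRF2 targets, 0.16 for the neuromuscular junction, 0.543 for cholesterol and 0.228 for the other 7; its mixed test passed for NRF2 and TGF-beta targets (0.001), fusion, neuromuscular junction, matrix, NF-kB and osteoblast lists (0.0286) and sarcomere (0.0425). Under the scalings, filters, blocks and left-out arrays run, the 11 called lists kept their direction. The transcription factor list was lost with array weights (0.0587) and ranged from 0.000633 to 0.0994 over left-out arrays; the proteasome list was lost above the median level (0.105) and ranged from 0.000354 to 0.0732; the cause was not tested.

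Other lists crossed the threshold in some settings. The stress list passed with the block (0.00739), above the median level (0.0271) and with array weights (0.00193), and ranged from 3.09e-08 to 1 over left-out arrays, turning direction without Htt siRNA replicate 1 (0.69), Htt siRNA replicate 3 (0.817) and scramble replicate 2 (1). Autophagy passed with the block (0.0383), above the median level (0.00505), with quantile normalization (0.00638) and array weights (0.0349), ranging from 0.0142 to 0.58. Fusion passed above the median level (0.0249) and with centred arrays (0.0433), ranging from 0.0211 to 0.399. NF-kB targets passed with the block (0.03), ranging from 0.0453 to 0.24, the interferon list with array weights (0.05, just under it before rounding), ranging from 1.45e-05 to 0.942, and endothelial markers ranged from 0.0371 to 0.335.

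Direction turned for 10 uncalled lists in 22 of 464 list results, none of them past the threshold. Above the median level these were adipocyte (0.802), p53 (0.933), ribosomal (0.939), macrophage (0.32), mitochondrial biogenesis (0.802) and oxidative phosphorylation (0.802) lists, and with repeated quantile normalization macrophage (0.94), mitochondrial biogenesis (0.94) and oxidative phosphorylation (0.946). Over left-out arrays the lists that turned ranged from 0.531 to 0.952 (Id and Notch, 0.825 without scramble replicate 1), 0.441 to 0.974 (p53, 0.974 without scramble replicate 1), 0.067 to 0.85 (ribosomal, 0.85 without Htt siRNA replicate 2), 0.651 to 0.981 (huntingtin partners, 0.981 without Htt siRNA replicate 1 and 0.893 without scramble replicate 2), 0.373 to 1 (growth factor, 1 without scramble replicate 2), 0.432 to 0.988 (macrophage, 0.985 without Htt siRNA replicate 3 and 0.942 without scramble replicate 1) and 0.309 to 0.981 (oxidative phosphorylation, 0.981 without Htt siRNA replicate 1 and 0.837 without scramble replicate 3). The planned exclusion of cross-hybridising probe sets by the ending of their names was not run because the probe sets carry plain numbers. Genes near the background (median gene mean 2.95, log2) have compressed fold changes, and no detection calls were used.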

Other observations

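Other than the test of array-wide scaling by repeated quantile normalization of the sarcomere list, which was planned before the result was seen, the tests in this part were chosen after it. Single genes outside the fixed lists are given as values, all chosen after their values were seen and none past the threshold over all genes. Higher values were found for Sgca, a sarcoglycan of the muscle membrane (log2 fold change 1.11 ± 0.17, SE), Mrln, a micropeptide regulator of the calcium pump (1.30 ± 0.20), the microRNA gene Mir133b (0.86 ± 0.14), the carbonic anhydrase Car3 (1.18 ± 0.19) and the myosin light chain Myl9 (1.05 ± 0.13), with adjusted p of 0.169 for the first 4 and 0.125 for Myl9. Lower values were found for the glutathione transferase-like Mgst2 (-0.67 ± 0.11, adjusted p = 0.169), the carbonyl reductase Cbr3 (-0.47 ± 0.08, adjusted p = 0.184) and the serpin genes Serpinb9b (-0.93 ± 0.14, adjusted p = 0.163) and Serpinb2 (-1.75 ± 0.44, adjusted p = 0.314). Cd53, a leukocyte tetraspanin, was lower (-1.42 ± 0.19, adjusted p = 0.163).

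The stress-response genes with the widest range had large spreads that did not follow the groups. The transporter gene Slc7a11 had log2 values of 6.41, 2.65 and 6.20 in Htt siRNA replicates 1, 2 and 3 and 7.65, 5.83 and 5.58 in scramble replicates 1, 2 and 3. The kinase-like Trib3 had 6.79, 3.01 and 7.16 against 7.57, 3.76 and 4.84, and the transcription factor Ddit3 9.06, 6.37 and 9.32 against 9.57, 5.79 and 7.35, in that order. With the group in the model, 542 genes passed limma's threshold for the stress level of the array, 28 of them in the list and 514 outside it. The 28 are built in, because the stress level is the mean of the list's own members.

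Cell division genes lay lower after Htt siRNA. The exact two-sided permutation p was 0.2 for the S phase and mitosis lists alike. Camera with an estimated correlation gave each an adjusted p = 0.429, and 0 of 38 mitosis genes passed limma's threshold adjusted over the list alone. The group difference of the S phase level was -0.73 ± 0.15 (log2, SE) with the stress covariate and -0.85 ± 0.39 without. That of mitosis was -0.61 ± 0.17 with it and -0.72 ± 0.37 without, so both differences remained. The stress level itself differed little between the groups (7.80 ± 0.92 with Htt siRNA against 7.57 ± 0.75 with scramble, SD, n = 3). The covariate could therefore shift these differences only slightly, and the fit argues only against the level of the stress list as their whole cause. Htt siRNA replicate 2, with Htt as low as its fellows, stood among the scramble arrays in the unadjusted levels of these lists. With the slope on the stress level removed, its S phase level relative to the 6-array mean was -0.25. Replicates 1 and 3 then stood at -0.55 and -0.30, and the scramble arrays at 0.24 to 0.52. That slope was fitted on these same 6 arrays with the group in the model, which draws arrays towards their group mean. The move of replicate 2 is thus partly built in and decides nothing. An effect of lower Htt, density, time of harvest and off-target action of the siRNA pool were not tested apart and stay open, because the design holds 1 pool and no culture record.

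The sarcomere and neuromuscular junction lists were higher after Htt siRNA. In camera with an estimated correlation each had an adjusted p = 0.429 (unadjusted 0.0365 and 0.0529). Repeated quantile normalization left the sarcomere median at 0.35 against 0.37, which decides nothing because it moved values by a median of only 0.02, but genes of the same mean level had a median log2 fold change of 0.04 (95% of level-matched lists between -0.02 and 0.09) for the sarcomere list and 0.02 (-0.07 to 0.10) for the neuromuscular junction list, whose own median was 0.43 (0.22 without scramble replicate 2), so a scaling that acts on level is argued against. With the stress covariate the group difference was 0.51 ± 0.10 (0.54 ± 0.13 without) for the sarcomere level. For the neuromuscular junction level it was 0.46 ± 0.09 (0.49 ± 0.13 without). As the stress level itself differed little between the groups, the covariate could shift these differences only slightly. The fit therefore argues only against the level of the stress list as their whole cause. Lower Htt, off-target action of the pool and differences in confluence, which also starts differentiation of C2C12 cells, were not tested apart and stay open. Markers of other cell types had medians between 0.04 and 0.10. Most of their members lay below the median level, where fold changes are compressed, so these medians form no firm contrast to the muscle lists.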
